A study of Mus musculus with 12 samples.

How the data were processed

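RNA was measured from primary mouse Müller glia, the main glial cells of the retina, after co-culture in transwell plates with primary cells of the retinal pigment epithelium (RPE). Per the labels, the RPE cells had received 100 nM PNU-282987 (PNU below), an agonist of the α7 nicotinic acetylcholine receptor, or the solvent DMSO, and the co-culture lasted 2 h or 6 h. The 12 libraries form 4 groups of 3, taken from the sample titles: PNU at 2 h, DMSO at 2 h, PNU at 6 h and DMSO at 6 h. The labels give 0.1% DMSO in one place and 1% in another, so the solvent concentration is not settled here. They call the samples biological replicates but do not say whether these came from separate animals or cultures, so all p-values measure only the spread between these samples.

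Per the labels' protocols, the authors selected poly(A) RNA, sequenced paired reads of 150 bp, trimmed them with fastp 0.23.2, aligned them to GRCm38 with STAR 2.5.2b and counted reads per gene with featureCounts of Subread 1.5.2. The submitters' processing notes also name DESeq2, with no role. The deposited values are raw whole-number counts per gene, 1 table per library, with no normalization. Whether the counting used the strand or multi-mapping reads, and which annotation release was used, is not given in the sources used here. Genes that overlap an antisense partner or share sequence with a close copy are therefore uncertain. The tables hold 49315 genes; 49056 gene identifiers were paired with a symbol through GENCODE M21, and 44823 had the identical position there. Library totals ran from 44332013 to 66518799 counts. Levels are given as CPM, counts scaled to the library's total, and at these depths 3 counts correspond to 0.0451 to 0.0677 CPM, which was taken as the floor of detection. This floor covers counting error only.

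Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 17164, libraries were scaled by TMM, and 1 quasi-likelihood model with robust estimation and 4 group means was fitted over all 12 libraries. The common biological coefficient of variation was 0.198. A total of 6 contrasts were tested: PNU against DMSO at 2 h, at 6 h and averaged over both times, the difference of the PNU effect between the times, and 6 h against 2 h within DMSO and within PNU. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05; fold changes are log2 values, and levels are CPM with the SD over 3 libraries. The standard error (SE) of a fold change was taken as its size divided by the square root of the test's F statistic, so it rests on the same spread as the p-value. A set of 38 gene lists was tested with camera of limma 3.58.1 at a preset correlation of 0.01, over lists with at least 5 tested members, and again with an estimated correlation and with fry. List p-values were adjusted over the lists of a contrast. Counts of genes at an unadjusted p under 0.05 are given as well. Chance alone would put a share of about 0.05 of all tested genes there.

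The groups, contrasts, lists, alternatives and the rule for named genes were chosen before the data were examined. For PNU against DMSO at each time, the rule takes the 10 risen and 10 fallen genes of largest log2 fold change that passed the test, had a mean of at least 1 CPM in the higher group and had all 3 PNU libraries on the same side of all 3 DMSO libraries. The other contrasts take up to 5 genes per direction, or, where fewer than 5 passed in all, the 10 genes of smallest p. It adds a fixed set of genes whatever their values, among them Chrna7, Gfap, Vim, Glul, Rlbp1, Sox9, Lin28a, Hbegf, Mki67 and Rpe65, and up to 4 passing members of each list. Of the 124 genes that the rule takes for time in PNU, most are not reported here, and neither are a few others. Members named from a list in which fewer passed, and all other genes named, were chosen after their values were seen.

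The pipeline was tested on simulated counts with 100 genes changed at each of 2 fold sizes. At 2-fold it recovered 69% of them for the 2 h contrast and 70% for the 6 h contrast, and at 4-fold 93% and 94%, with 11 and 7 false calls. For the averaged contrast it recovered 85% and 95%, for the time difference of the PNU effect 45% and 89%, for time in DMSO 72% and 93%, and for time in PNU 68% and 94%. The simulated replicates varied alike, which the real ones did not.

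The alternatives were 2 other scalings, DESeq2 1.42.0, limma-voom, no filter and a stricter filter, a fit of the contrast's libraries alone, the replicate number as a block, estimation without robustness, exclusion of mitochondrially encoded genes, a test against a minimum fold of 1.2, and each library left out in turn. After the data were seen, 3 more were added: removal of each library's GC-content trend, summing of libraries of 1 group that were nearly identical (a pairwise coefficient of variation under 0.05), and exclusion of both libraries that stood apart from their groups. Replicates were compared by chi-square before averaging. The near-identical pairs differed by more than counting noise, as separate libraries of 1 culture also would, so this does not show that they came from separate cultures. Each library was counted as a replicate in the reported tests because the labels number it as one. No library was left out of those tests. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.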

Results

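Gene expression was measured by poly(A) RNA sequencing in 12 libraries of cultured cells labelled as mouse Müller glia, 3 in each of 4 groups. The glia had shared medium across a transwell membrane with RPE cells given PNU-282987 (PNU) or DMSO, for 2 h or 6 h. The design compares the glia facing PNU-treated RPE with those facing DMSO-treated RPE at the same time, and so asks whether signals from the treated epithelium change expression in the glia. Totals ranged from 44332013 counts (DMSO at 6 h, replicate 1) to 66518799 counts (PNU at 2 h, replicate 3). Mitochondrially encoded genes took 0.738% to 1.34% of counts. Thbs1, a secreted matrix protein, was the most abundant transcript in every library, with 1.21% to 1.72% of counts.

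The cultures expressed mesenchymal and matrix genes at high levels and several Müller glia markers at low levels. Across the 12 libraries, Col1a1, a fibrillar collagen chain, stood at 3432 to 5112 CPM, Acta2, smooth muscle actin, at 1454 to 2468 CPM, and Pdgfrb, a pericyte and fibroblast receptor, at 928 to 1383 CPM. Vim, an intermediate filament of glia and mesenchyme, stood at 5869 to 7545 CPM. Glul, the glutamine synthetase of Müller glia, stood at 62.1 to 93.8 CPM. Slc1a3, a glial glutamate transporter, reached at most 3.70 CPM, Rlbp1, the retinaldehyde-binding protein of Müller glia, at most 0.296 CPM, and Aqp4, the glial water channel, at most 0.214 CPM. Rpe65, the visual-cycle isomerase of RPE cells, was at or under 0.0462 CPM in every library, and Ptprc, the pan-leukocyte marker CD45, at or under 0.233 CPM. Of the 22 genes in the Müller glia list, 12 had a median over 1 CPM across the libraries and 3 over 100 CPM. In the fibroblast list these numbers were 15 and 8 of 20. The name Müller glia thus rests on the labels, and these counts over whole cultures do not show in which cell type a gene changed.

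Replicates varied unevenly. PNU at 2 h replicates 2 and 3, PNU at 6 h replicates 2 and 3, and all 3 DMSO libraries at 6 h were nearly identical, with pairwise coefficients of variation of 0.0162 to 0.0222, while other pairs of the same group ranged from 0.138 to 0.355. The labels do not say whether such libraries came from separate cultures. If they did not, at most 2 cultures stand behind the 3 libraries of each PNU group and 1 behind those of DMSO at 6 h, n = 3 overstates the replication and the p-values are too small. DMSO at 2 h replicate 3 lay nearest to PNU at 2 h replicate 1, with a root mean square log2 distance of 0.405, against a mean of 0.859 to the other DMSO libraries at 2 h. PNU at 6 h replicate 1 lay nearest to DMSO at 6 h replicate 3, at 0.485, against a mean of 0.706 to the other PNU libraries at 6 h. The first principal component held 49.6% of the variance and placed DMSO at 2 h replicate 3 beside the PNU libraries and PNU at 6 h replicate 1 beside the DMSO libraries. Libraries also differed in the Y-linked gene Ddx3y. At 6 h it stood at 0.14, 7.30 and 6.67 CPM in PNU replicates 1, 2 and 3 and at most 0.138 CPM with DMSO. At 2 h it stood at 2.33 CPM in PNU replicate 1, 5.05 CPM in DMSO replicate 3 and at most 0.0889 CPM otherwise. A PNU effect at 6 h or averaged over both times therefore cannot be told apart from a difference between cultures. At 2 h such a difference is not excluded either.

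**Figure D1:**
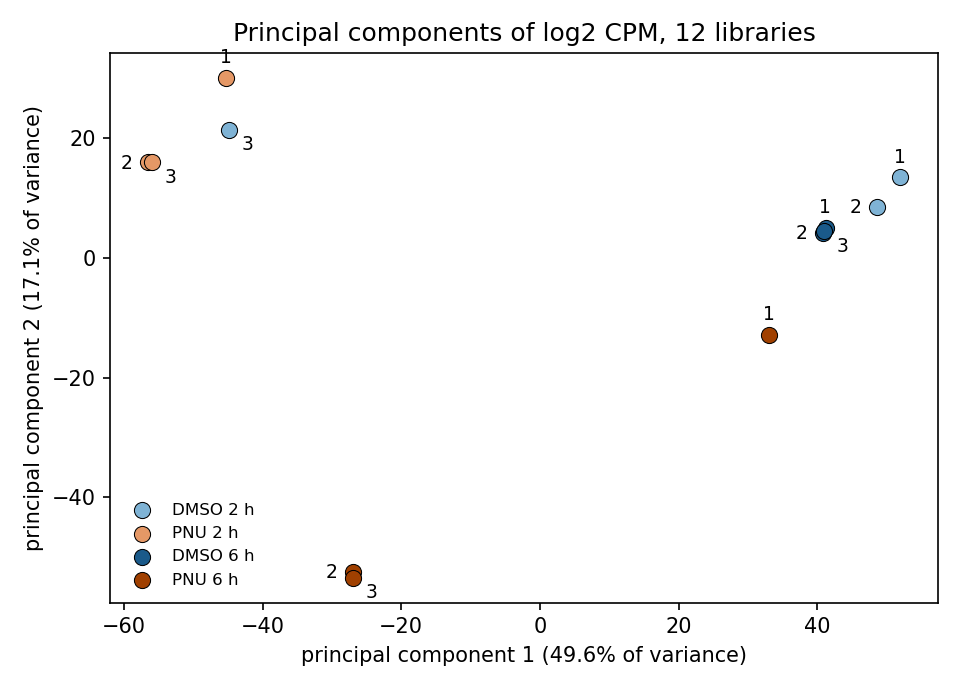
Each point is 1 library, placed by the first (x axis, 49.6% of variance) and second (y axis, 17.1%) principal component of log2 CPM, coloured by group and marked with its replicate number. DMSO at 2 h replicate 3 sits at -44.8 on the first component, near the PNU libraries at 2 h, and PNU at 6 h replicate 1 sits at 33.0, near the DMSO libraries.

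At 2 h, Irs2, an adaptor of insulin and IGF receptors (ENSMUSG00000038894, GRCm38 chromosome 8, 10984681 to 11008458), rose from 29.8 ± 5.59 to 64.0 ± 2.91 CPM (SD, n = 3 per group), a log2 fold change of 1.10 ± 0.12 (SE). Irs1, a related adaptor (ENSMUSG00000055980, chromosome 1, 82233101 to 82291416), fell from 92.2 ± 39.6 to 28.4 ± 1.81 CPM. Dot1l, the histone H3 lysine 79 methyltransferase, rose from 74.4 ± 25.7 to 169 ± 12.6 CPM, and Itgb3, the integrin β3 chain, from 63.1 ± 14.0 to 128 ± 13.5 CPM. Snai2, a transcription factor of epithelial-mesenchymal transition, fell from 54.3 ± 21.4 to 19.9 ± 2.22 CPM.

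With edgeR, 36 genes rose and 14 fell at 2 h among 17164 tested, and 5149 had an unadjusted p under 0.05. The other named risen genes were Chst8, a GalNAc-4-sulfotransferase (log2 fold change 2.17 ± 0.33), Ramp3, an accessory protein of calcitonin-family receptors (1.54 ± 0.22), and Arid5a, an RNA-binding protein that stabilises inflammatory transcripts (1.44 ± 0.22). Risen as well were Apol8 (1.28 ± 0.22), Prag1 (1.24 ± 0.19), Cnnm4, a magnesium transporter (1.02 ± 0.13), and Ddit4, a stress-induced inhibitor of mTORC1 (0.92 ± 0.15). The other named fallen genes were Agtr1a, the angiotensin II receptor (-3.52 ± 0.61), Kprp (-2.01 ± 0.28) and Hcar1, the lactate receptor (-1.47 ± 0.26). Fallen as well were Tlcd2 (-1.13 ± 0.18), Edn1, endothelin 1 (-1.05 ± 0.16), Rnd3 (-1.01 ± 0.15), Fhl2, a LIM-domain cofactor (-0.86 ± 0.14), and Cxcl1, a neutrophil chemokine (-0.76 ± 0.11). Smad3, a TGF-β signal transducer, rose by 0.49 ± 0.08 and Cspg4, the NG2 proteoglycan of pericytes, by 0.86 ± 0.15. Adjusted p-values of these 22 named genes lay between 0.0181 for Irs2 and 0.0435 for Hcar1. DESeq2 called 2511 genes, of which 985 were higher and 1526 lower, and limma-voom 75. When near-identical libraries were summed and counted once, edgeR called 0 genes, with 1402 at an unadjusted p under 0.05. A test against a minimum fold of 1.2 and a fit of the libraries at 2 h alone also gave 0, with 2846 and 2926.

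The count at 2 h depended on single libraries. Without DMSO replicate 3 it was 7724, with 3686 higher and 4038 lower, and without PNU replicate 1 it was 130. Without DMSO replicate 1 or DMSO replicate 2 it was 1 each time. Without PNU replicate 2 or PNU replicate 3, edgeR called 0 genes, with 3528 and 3423 at an unadjusted p under 0.05. All 22 named genes that passed lost their call without PNU replicate 2, PNU replicate 3 or DMSO replicate 1, 21 without DMSO replicate 2, 2 without PNU replicate 1 and 0 without DMSO replicate 3. DMSO replicate 3 stood between the groups for Dot1l (103 CPM against 65.4 and 54.5 in the other DMSO libraries), Irs1 (47.1 against 122 and 108 CPM) and Snai2 (29.7 against 64.5 and 68.7 CPM).

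Cell-cycle genes stood higher as a group with PNU at 2 h. In the G2 and M phase list, 54 of 55 members had a positive fold change, with a median log2 value of 0.370. A total of 0 passed singly in edgeR, over all genes or adjusted over the list alone. Camera gave an adjusted p of 1.66e-07 (adjusted p = 0.535 with an estimated correlation). In the S phase list 47 of 49 members were positive, the median was 0.377 and 0 passed singly in either way (camera adjusted p = 5.88e-07; adjusted p = 0.535 with an estimated correlation). Aurkb, the mitotic kinase Aurora B, stood at 55.6 ± 2.28 against 38.1 ± 15.1 CPM, and E2f8, a repressor of the cell-cycle E2F family, at 22.6 ± 1.59 against 12.5 ± 5.85 CPM. Within the DMSO group, replicate 3 held Top2a, the topoisomerase of mitotic chromosomes, at 218 CPM, against 79.2 and 104 CPM in replicates 1 and 2 and 197 to 200 CPM with PNU.

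The interferon response list was lower with PNU at 2 h, with 1 of 31 tested members positive and a median log2 value of -0.716. A total of 0 members passed singly in edgeR, 9 fell when adjusted over the list alone, and camera gave an adjusted p of 5.88e-07 (adjusted p = 0.435 with an estimated correlation). Ifit3, an interferon-induced antiviral gene, stood at 2.34 ± 0.495 CPM with PNU and 9.60 ± 6.22 CPM with DMSO, where replicate 3 held 2.56 CPM and replicates 1 and 2 held 14.3 and 11.9 CPM.

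Other lists were also called up by camera at 2 h. The unfolded protein and integrated stress response list had a median of 0.182, with 1 member, Ddit4, risen and 47 not passing, and 19 risen when adjusted over the list alone (camera adjusted p = 6.39e-07; adjusted p = 0.435 with an estimated correlation). Immediate early genes, which respond to stimulation within minutes, had a median of 0.445, with 0 of 31 passing singly, and 18 risen and 6 fallen when adjusted over the list alone (camera adjusted p = 0.000216; adjusted p = 0.435 with an estimated correlation). Their members went both ways: Atf3, a stress-induced transcription factor, stood at 12.5 ± 1.51 against 3.01 ± 2.56 CPM and Fos, a subunit of the AP-1 factor, at 24.3 ± 0.998 CPM with PNU and 62.8, 56.6 and 30.5 CPM in the 3 DMSO libraries. The EGF receptor and ERK list had 0 of 32 passing, and 5 risen and 3 fallen over the list alone (median 0.384, camera adjusted p = 0.00209; adjusted p = 0.435 with an estimated correlation). Heat shock proteins had 0 of 25 passing and 1 risen over the list alone (0.208, 0.00286 and 0.513, in the same order). Circadian clock genes had 0 of 23 passing, with 7 risen and 1 fallen over the list alone (0.190, 0.00380 and 0.435). Chromatin and DNA methylation regulators had 0 of 42 passing, with 8 risen and 2 fallen over the list alone (0.152, 0.0121 and 0.435). In all, 8 of the 38 lists were called up and 1 down at 2 h. The number called was 18 without DMSO replicate 3 and 14 without PNU replicate 1. With an estimated correlation it was 0.

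**Figure D2:**
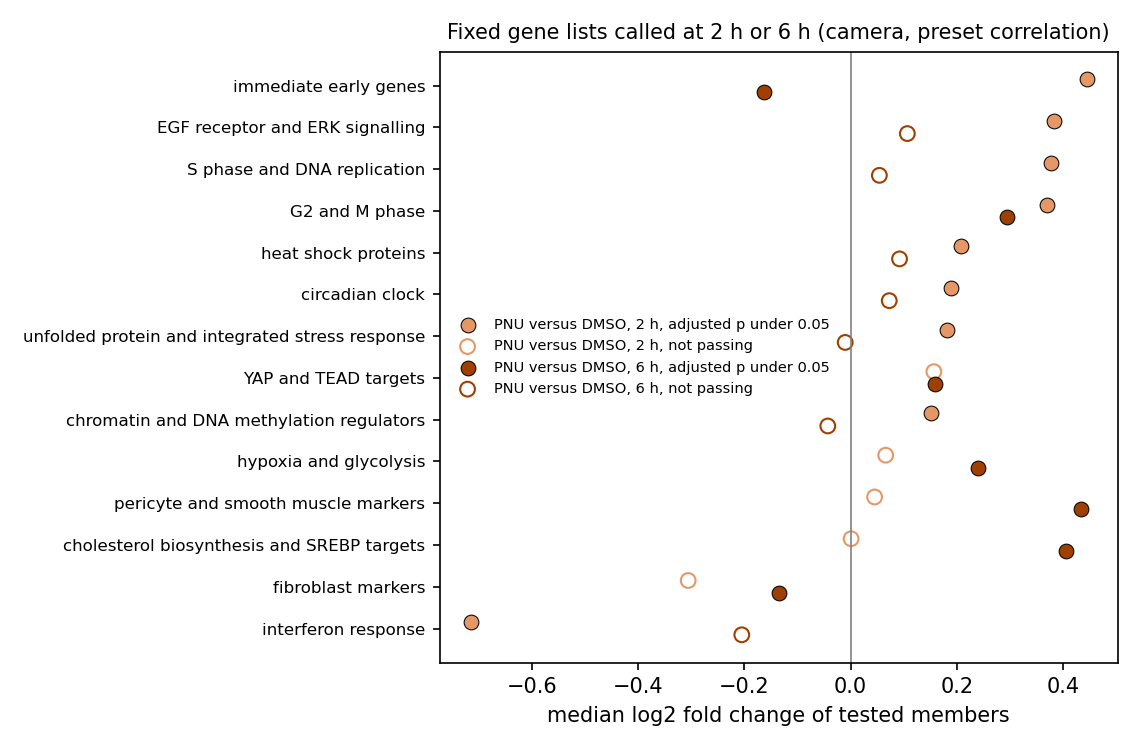
Each point gives the median log2 fold change (x axis) of the tested members of a fixed gene list, for PNU against DMSO at 2 h (light) and 6 h (dark). Filled points passed camera at an adjusted p of 0.05 with the preset correlation, and none of those shown passed with an estimated correlation; the interferon list lies lowest at 2 h, at -0.716.

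At 6 h, Egr1, a transcription factor induced by growth factors, fell from 224 ± 1.09 to 89.2 ± 29.2 CPM (SD, n = 3 per group; log2 fold change -1.33 ± 0.19, SE), and Fos, its partner among immediate early genes, fell from 61.6 ± 2.31 to 18.7 ± 5.37 CPM. Penk, the enkephalin precursor (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819), fell from 37.0 ± 1.17 to 6.86 ± 2.24 CPM, with all 3 PNU libraries between 5.45 and 9.44 CPM. Igfbp2, an IGF-binding protein (ENSMUSG00000039323, chromosome 1, 72824503 to 72852474), rose from 3.08 ± 0.376 to 157 ± 93.5 CPM, with 49.1, 206 and 216 CPM in the 3 PNU libraries. Sp7, the osteoblast transcription factor osterix, fell from 15.4 ± 0.530 to 3.07 ± 1.21 CPM.

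With edgeR, 98 genes rose and 83 fell at 6 h, and 2683 had an unadjusted p under 0.05. Other named risen genes were Tmem171 (0.0324 ± 0.0130 CPM with DMSO and 0.209, 1.85 and 1.55 CPM in the 3 PNU libraries), Asb5 (log2 fold change 4.45 ± 0.80), Esrp2, an epithelial splicing factor (3.10 ± 0.62), F11r, a tight-junction protein (2.84 ± 0.54), Kcnh1, a potassium channel (2.82 ± 0.59), Fam84b (2.76 ± 0.48), Wnt4, a Wnt ligand (2.70 ± 0.48), and Slc9a7, a sodium-proton exchanger (2.49 ± 0.51). Most were scarce: 6 of these 8, all except Asb5 and Wnt4, had a mean with PNU no higher than that of Slc9a7, 1.92 ± 1.18 CPM. The other named fallen genes were Adipoq, the adipocyte hormone adiponectin (1.93 ± 0.203 CPM with DMSO, 0.0258 ± 0.0323 CPM with PNU), Kcp, a secreted BMP regulator (log2 fold change -3.28 ± 0.49), Lrrn3 (-2.56 ± 0.40), Cyp1a1, a target of the aryl hydrocarbon receptor (-2.33 ± 0.48), Chst13 (-2.16 ± 0.37), Fstl4 (-2.05 ± 0.37) and Nlrc5, a regulator of MHC class I genes (-1.56 ± 0.30). For Tmem171 and Adipoq no fold is given, because the lower mean lay under the floor of detection. Adjusted p-values of these genes and those of the preceding paragraph ranged from 0.00276 for Sp7 to 0.0491 for Kcnh1. DESeq2 called 923 genes and limma-voom 178. With near-identical libraries summed and counted once, edgeR called 0 genes, with 240 at an unadjusted p under 0.05.

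Each library at 6 h moved the count by more than 1.5 times. It was 1057 without PNU replicate 1, 38 without PNU replicate 2 and 35 without PNU replicate 3. It was 35 without DMSO replicate 1, 22 without DMSO replicate 2 and 26 without DMSO replicate 3. Of the 40 genes taken by the naming rule that passed, 31 lost their call without PNU replicate 2, 32 without PNU replicate 3, 31, 35 and 34 without DMSO replicates 1, 2 and 3, and 0 without PNU replicate 1. PNU replicate 1 stood nearer to DMSO for Asb5, with 1.69 CPM against 26.7 and 24.4 CPM in the other PNU libraries, and for Wnt4, with 2.85 against 9.47 and 9.67 CPM.

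Genes of cholesterol synthesis stood higher as a group with PNU at 6 h. In this list 34 of 36 members were positive, the median was 0.406, 0 passed singly over all genes in edgeR and 11 rose when adjusted over the list alone (camera adjusted p = 1.15e-10; adjusted p = 0.493 with an estimated correlation). Fdps, which makes farnesyl diphosphate, stood at 67.4 ± 20.8 against 40.0 ± 0.341 CPM, and Hmgcs1, an early enzyme of the pathway, at 187 CPM in PNU replicate 1 and 92.4 and 88.4 CPM in PNU replicates 2 and 3, against 81.6 to 87.8 CPM with DMSO. In the hypoxia and glycolysis list 34 of 40 members were positive, with 0 passing and, adjusted over the list alone, 9 risen and 1 fallen (median 0.241, camera adjusted p = 0.000155; adjusted p = 0.441 with an estimated correlation). Pgk1, a glycolytic kinase, stood at 536 ± 19.1 against 351 ± 3.94 CPM. All 55 members of the G2 and M phase list were positive, with a median of 0.295 and 0 passing in either way (camera adjusted p = 5.92e-06; adjusted p = 0.735 with an estimated correlation). YAP and TEAD targets had 0 of 28 passing and 2 risen over the list alone (median 0.159, camera adjusted p = 0.0198; adjusted p = 0.493 with an estimated correlation). This call ended without PNU replicate 2 (0.0659) or PNU replicate 3 (0.129), and with near-identical libraries summed (0.115; over all its alternatives 6.94e-07 to 0.493). The hypoxia call ended without PNU replicate 1 (adjusted p = 0.126; over all its alternatives 3.63e-06 to 0.441).

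The immediate early list was called down with PNU at 6 h, although 14 of 31 members had a positive fold change. A total of 4 fell and 27 did not pass, and 1 rose and 7 fell when adjusted over the list alone. The list median was -0.163 and camera gave an adjusted p of 0.000451 (adjusted p = 0.493 with an estimated correlation). The fallen members were Fos, Egr1, Ier2 (-1.48 ± 0.18) and Arc, a gene of synaptic activity (-0.95 ± 0.18). In the EGF receptor and ERK list, which was not called (camera adjusted p = 0.343), Spry4 (-1.11 ± 0.14) and Dusp6 (-0.72 ± 0.12), both feedback inhibitors of ERK signalling, fell with Egr1, and Egfr, the EGF receptor itself, rose by 0.66 ± 0.11. The call on Arc ended after removal of the GC-content trend and without any library except PNU replicate 1 (adjusted p over its alternatives 0.000264 to 1.0).

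In the pericyte and smooth muscle list at 6 h, Cnn1, a smooth muscle calponin (1.10 ± 0.22), and Mcam, a pericyte adhesion molecule (0.47 ± 0.08), rose, 10 of 12 members did not pass, and 3 rose when adjusted over the list alone (median 0.435, camera adjusted p = 0.0132; adjusted p = 0.441 with an estimated correlation). In the fibroblast list the matrix proteoglycans Lum and Dcn (-1.12 ± 0.23) fell, 17 of 19 did not pass, and 3 fell when adjusted over the list alone (median -0.135, camera adjusted p = 0.0198; adjusted p = 0.493 with an estimated correlation). Lum was scarce, at 0.918 ± 0.166 CPM with DMSO and, under the floor of detection, 0.0371 ± 0.0382 CPM with PNU. The pericyte call ended without PNU replicate 1 (adjusted p = 0.143; over all its alternatives 0.00319 to 0.441) and the fibroblast call with the stricter filter (0.108; 0.00526 to 0.493). Loxl2, a collagen crosslinking enzyme (1.13 ± 0.21), Inhbb, an activin subunit (1.16 ± 0.16), Itgb5, an integrin chain (0.68 ± 0.09), Hspb1, a small heat shock protein (0.83 ± 0.16), Lgr4, an R-spondin receptor (0.44 ± 0.09), and Csf1r, the receptor of macrophage colony-stimulating factor (1.81 ± 0.29), rose. Sema3c, a guidance cue (-0.83 ± 0.14), Maml3, a Notch coactivator (-0.73 ± 0.14), Klf9, a glucocorticoid-induced factor (-0.57 ± 0.10), and Dnmt3a, a DNA methyltransferase (-0.33 ± 0.07), fell. In all, 5 lists were called up and 2 down at 6 h, and 0 with an estimated correlation.

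Sox9, Hbegf, Chrna7, Mki67, Vim and Glul, all named in advance, did not pass at 2 h or 6 h in edgeR. Sox9, a transcription factor of glia and progenitors, stood at 253 ± 46.1 CPM with PNU and 121 ± 56.5 CPM with DMSO at 2 h (log2 fold change 1.07 ± 0.25, adjusted p = 0.0636), where DMSO replicate 3 held 186 CPM. Without that library, Sox9 passed with 1.52 (adjusted p = 9.47e-06; over all its alternatives 1.24e-06 to 0.537). Hbegf, a ligand of the EGF receptor, stood at 205 ± 28.6 against 64.9 ± 73.3 CPM at 2 h (adjusted p = 0.115). DMSO replicate 3 held 150 CPM and the other DMSO libraries 24.7 and 20.5 CPM, and Hbegf passed without replicate 3 (3.18, adjusted p = 2.04e-05; 7.11e-09 to 0.537). Chrna7, which encodes the receptor PNU binds, stood at 0.436 ± 0.162 against 0.171 ± 0.140 CPM at 2 h (adjusted p = 0.106) and passed without DMSO replicate 3 (2.22, adjusted p = 0.00154; 0.00129 to 0.537). Mki67, a marker of cycling cells, stood at 142 ± 11.7 against 96.3 ± 47.9 CPM (adjusted p = 0.219) and passed without DMSO replicate 3 (1.05, adjusted p = 0.00311; 2.11e-06 to 0.583). Without DMSO replicate 3, however, 7724 genes passed at 2 h, against 50 with all libraries. Passing there therefore does little to set Sox9, Hbegf, Chrna7 and Mki67 apart from other genes. That library was also singled out because it lay toward the PNU libraries, so these passing results are inflated by selection. Vim (0.14 ± 0.09 at 2 h, 0.12 ± 0.09 at 6 h) and Glul (0.10 ± 0.12 and 0.19 ± 0.12) did not pass. Gfap, the intermediate filament of reactive glia, averaged at most 0.229 CPM in any group. Lin28a had 0 counts in all 12 libraries. These, Rlbp1 and Rpe65 were too scarce to test.

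**Figure D3:**
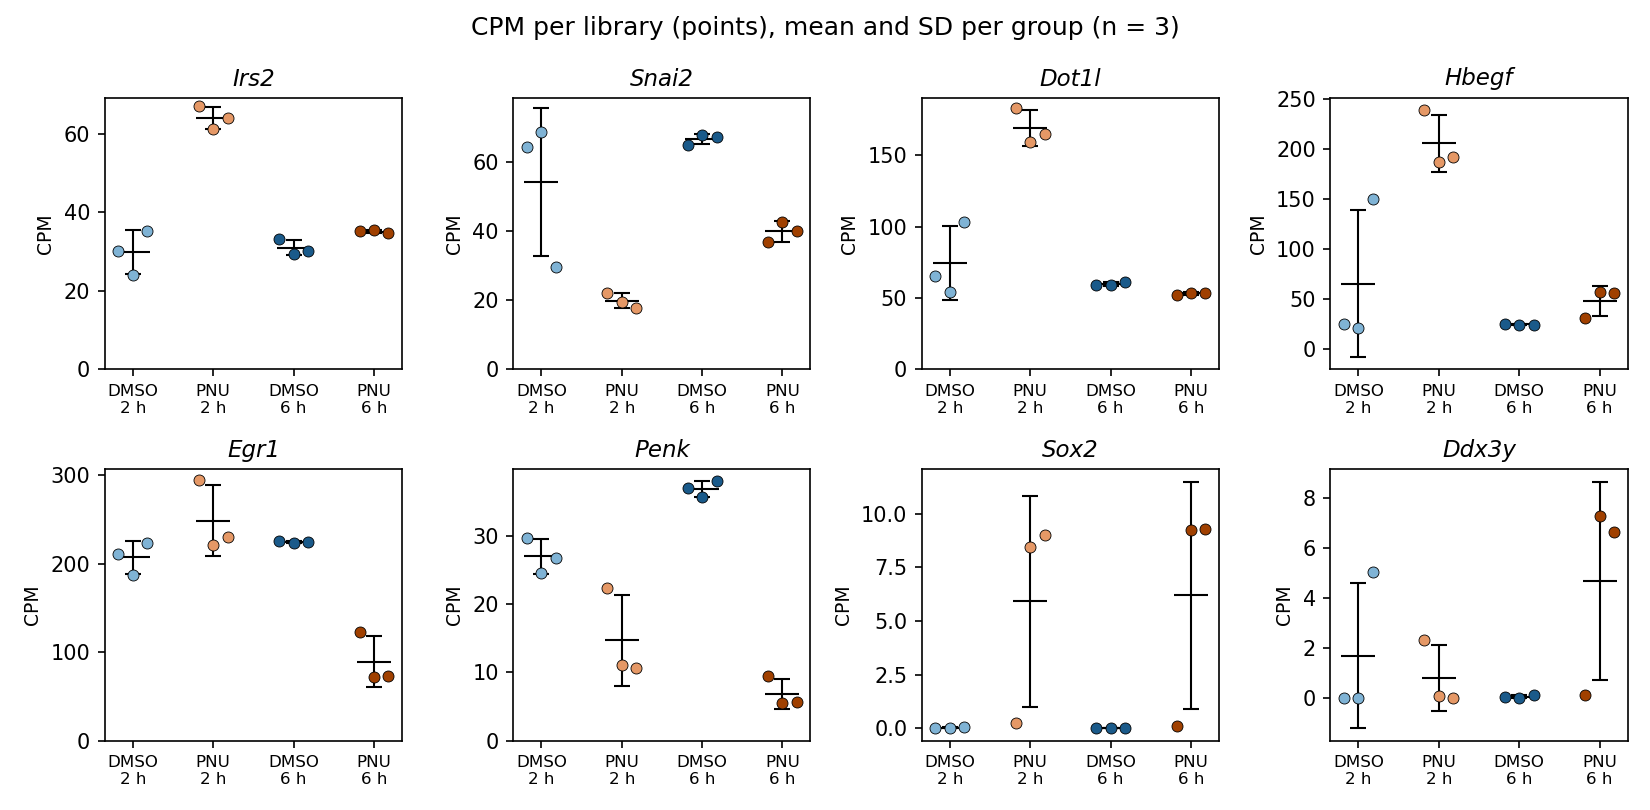
Points are CPM (y axis) of single libraries by group, with bars for the mean and SD of n = 3. Irs2 separated PNU from DMSO at 2 h in every library, as the rule for named genes requires. DMSO at 2 h replicate 3 lay toward the PNU values for Hbegf, Snai2 and Dot1l. Sox2 stood at 8.45 to 9.29 CPM in 4 of the 6 PNU libraries and at 0.254 CPM or less elsewhere.

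Lists of retinal cell identity were not called at either time. The Müller glia list gave camera adjusted p-values of 0.552 at 2 h and 0.801 at 6 h, reactive gliosis 0.0710 and 0.801, and retinal progenitor factors 0.190 and 0.0916. At 6 h the Müller glia median (0.102) and mean (0.629) were above 0 while the test pointed down. RPE markers gave 0.992 and 0.791, photoreceptor markers 0.814 and 0.770, inner retinal neuron markers 0.158 and 0.777, and microglia and macrophage markers 0.992 and 0.493. Within the progenitor and lens lists a few genes were present in some libraries only. Sox2, a factor of neural progenitors, stood at 8.45 and 9.02 CPM in PNU at 2 h replicates 2 and 3 and at 9.22 and 9.29 CPM in PNU at 6 h replicates 2 and 3. It stood at no more than 0.254 CPM in the other 8 libraries.

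Averaged over both times, 718 genes were higher and 827 lower with PNU in edgeR, and 5600 had an unadjusted p under 0.05. The largest risen named genes were high in replicates 2 and 3 of both PNU groups and not in replicate 1. Cryaa, a lens crystallin, stood at 11.5, 11.0, 8.11 and 8.93 CPM in those 4 libraries, at 0.208 and 0.0698 CPM in the other PNU libraries and at 0 in all DMSO libraries at 6 h. Zbtb8b, Six3os1 and Hmx1, an eye-development homeobox gene, followed the same libraries, with adjusted p-values of 0.0242, 0.0146 and 0.0180. Lrrc17 (-3.28 ± 0.87), Kcp (-2.76 ± 0.34), Meox1, a mesodermal homeobox gene (-2.72 ± 0.55), G0s2, an inhibitor of lipolysis (-2.60 ± 0.43), and Agtr1a (-2.51 ± 0.40) fell. The average called 10 lists up and 2 down (0 with an estimated correlation), among them interferon response with 4 members fallen (camera adjusted p = 6.17e-05) and hypoxia and glycolysis with 13 risen and 1 fallen (0.000844).

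The count of 1545 rested on single libraries too. It was 7672 without DMSO at 2 h replicate 3, and 495 and 308 without DMSO at 2 h replicates 1 and 2. It was 933, 98 and 107 without PNU at 2 h replicates 1, 2 and 3, and 3625, 176 and 142 without PNU at 6 h replicates 1, 2 and 3. It was 125, 126 and 139 without DMSO at 6 h replicates 1, 2 and 3. DESeq2 called 3225 genes and limma-voom 996, and with near-identical libraries summed edgeR called 0, with 955 at an unadjusted p under 0.05.

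The PNU effect differed between 6 h and 2 h for 6 genes in edgeR (3 higher and 3 lower at 6 h), with 1936 at an unadjusted p under 0.05. Parm1, a membrane mucin, stood 0.50 ± 0.09 higher with PNU at 2 h (adjusted p = 0.0506) and rose by 1.42 ± 0.09 at 6 h. Cxcl1 fell by 0.76 ± 0.11 at 2 h and stood 0.38 ± 0.10 higher with PNU at 6 h. Apln, the ligand of the apelin receptor, stood at 26.4 ± 2.45 and 25.9 ± 1.77 CPM with PNU and DMSO at 2 h and at 14.9 ± 1.31 and 29.3 ± 0.248 CPM at 6 h. For Dot1l and Sox9 the difference between times was -1.35 ± 0.25 and -1.19 ± 0.35 and did not pass (adjusted p = 0.0907 and 0.263). The number was 2947 without DMSO at 2 h replicate 3, 141 without PNU at 6 h replicate 1 and 15 without DMSO at 2 h replicate 1. It was 0 without DMSO at 2 h replicate 2, without PNU replicate 2 or 3 at either time, or without any 1 DMSO library at 6 h; unadjusted p-values under 0.05 then numbered 1365 to 1650. DESeq2 called 279 genes and limma-voom 4. All 6 calls ended when near-identical libraries were summed, under a minimum fold of 1.2 and with the replicate number as a block. In these fits edgeR called 0 genes, with 209, 1148 and 1929 at an unadjusted p under 0.05. In the lists, immediate early genes (median -0.676, camera adjusted p = 1.10e-13; adjusted p = 0.173 with an estimated correlation) and cholesterol genes (0.456, 2.18e-09 and 0.540) had the smallest p of the 8 lists called, 2 up and 6 down, of which 0 were called with an estimated correlation.

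Ramp3, Dysf, a membrane repair protein, and Nup210, a nuclear pore protein, rose at both times, 3 genes against 0.206 for independent lists, and 0 of the fallen genes were shared. Of the 36 genes risen at 2 h, 29 had a positive fold change at 6 h, and of the 98 risen at 6 h, 77 had one at 2 h. Of the 14 genes fallen at 2 h, 13 had a negative fold change at 6 h, and of the 83 fallen at 6 h, 53 had one at 2 h. The libraries of the 2 times are not known to be unrelated, since replicates 2 and 3 of both PNU groups shared transcripts such as Sox2 and Cryaa that stood far lower elsewhere, so no test of this agreement is given. Across genes, which are not independent replicates, fold changes at the 2 times correlated with a Spearman coefficient of 0.438. The share with the same sign over all tested genes was not counted. The counts above therefore do not show an agreement particular to the called genes.

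Time alone changed no gene past the threshold in DMSO. Between 2 h and 6 h edgeR called 0 genes, limma-voom 0 and DESeq2 23. A total of 818 genes had an unadjusted p under 0.05, less than a share of 0.05 of the 17164 tested. The smallest adjusted p was 0.441. Stc1, a secreted regulator of calcium and phosphate, stood at 1.98 ± 0.237 CPM at 2 h and 3.94 ± 0.339 CPM at 6 h with this p. Ric3, a chaperone of nicotinic receptors, stood at 0.829 ± 0.115 and 1.80 ± 0.239 CPM, and Il33, an alarmin cytokine, at 0.763 ± 0.216 and 1.83 ± 0.340 CPM. Olfm2, Satb1, Lypd1, Fbxo16, Gpr176 and Prss35 shared that p, followed by Pex11a (0.472). The nicotinic acetylcholine receptor list, which also holds receptor partners such as Ric3 and the cholinesterases Ache and Bche, was called up. A total of 10 of 12 members were positive, with a median of 0.325. Over all genes 0 passed, and 2 rose when adjusted over the list alone (camera adjusted p = 5.00e-07, adjusted p = 0.0166 with an estimated correlation). S phase (median -0.415, camera adjusted p = 1.03e-15; adjusted p = 0.881 with an estimated correlation), cholesterol (-0.338, 3.08e-15 and 0.808), G2 and M phase (-0.308, 2.90e-08 and 0.881) and stress response genes (-0.106, 0.000532 and 0.881) were called down and mitochondrially encoded genes up (0.168, 0.0109 and 0.881). Without DMSO at 2 h replicate 3, 4 genes passed, the G2 and M phase median was 0.0385 (adjusted p = 0.233; over all its alternatives 5.41e-15 to 0.881), and the S phase (0.151; 3.69e-17 to 0.881) and stress response calls (0.919; 2.34e-06 to 0.919) ended. The mitochondrial median was -0.0626 without DMSO at 2 h replicate 1 (0.889; 1.46e-05 to 0.889), and that call also ended without DMSO at 6 h replicate 2 (0.0824).

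In PNU, 1273 genes were higher and 1486 lower at 6 h than at 2 h in edgeR. The balance turned with upper-quartile scaling, to 1880 higher and 1102 lower. The libraries of the 2 times also differed in the Y-linked gene Ddx3y. It stood at 2.33, 0.0889 and 0.0154 CPM in PNU replicates 1, 2 and 3 at 2 h, and at 0.14, 7.30 and 6.67 CPM at 6 h. A change with time in PNU therefore cannot be told apart from a difference between cultures. Immediate early genes had the lowest median of the lists called, with 1 of 31 risen and 18 fallen (2 and 20 adjusted over the list alone; median -1.0, camera adjusted p = 1.25e-11; adjusted p = 0.205 with an estimated correlation). Egr3, a growth-factor-induced transcription factor, fell from 39.9 ± 9.39 to 3.61 ± 0.641 CPM and Egr2, its relative, from 89.6 ± 34.7 to 8.55 ± 0.365 CPM. In DNA replication 24 of 49 genes fell and 25 did not pass, with 39 fallen over the list alone (camera adjusted p = 9.41e-15; adjusted p = 0.744 with an estimated correlation). Uhrf1, which couples replication to DNA methylation (-0.81 ± 0.16), and Cdt1, a licensing factor (-0.96 ± 0.21), were among them. In the stress response list 1 gene rose and 23 fell, with 2 and 25 over the list alone (camera adjusted p = 7.99e-12; adjusted p = 0.405 with an estimated correlation). Its members of smallest p were Cars, a tRNA synthetase (-0.82 ± 0.08), Mthfd2, a folate enzyme of mitochondria (-1.12 ± 0.12), and Slc7a5, an amino acid transporter (-1.50 ± 0.17). The nicotinic receptor list, which also holds receptor partners such as Ric3 and the cholinesterases Ache and Bche, showed 7 risen and 1 fallen of 12. The numbers were the same over the list alone (camera adjusted p = 0.00134, adjusted p = 0.0959 with an estimated correlation). Risen were the receptor subunits Chrna1, of muscle (2.30 ± 0.44), and Chrng, and also Ric3 (1.49 ± 0.19), Ly6e, Lynx1, Bche and Ache.

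Chromatin regulators had 14 of 42 fallen, with 3 risen and 17 fallen over the list alone (camera adjusted p = 0.000174; adjusted p = 0.0959 with an estimated correlation), among them Dnmt3a (-0.50 ± 0.07) and Kdm6b, a histone demethylase (-0.75 ± 0.10). In the interferon list 4 of 31 rose, in either way of adjusting (camera adjusted p = 0.000301; adjusted p = 0.744 with an estimated correlation), among them Gbp7 (1.76 ± 0.43). Circadian genes (7 of 23 fallen, 1 risen), heat shock proteins (4 of 25 fallen), EGF receptor and ERK genes (9 of 32 fallen, 1 risen) and G2 and M phase genes (2 of 55 fallen) were also called down by camera. With an estimated correlation their adjusted p was 0.405, 0.744, 0.405 and 0.790.

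Further genes that differed between 6 h and 2 h in PNU were Sox9 and Lif, a gliosis cytokine. Sox9 was lower at 6 h, at 67.9 ± 4.24 against 253 ± 46.1 CPM (-1.90 ± 0.26), and so was Lif, at 22.0 ± 6.00 against 131 ± 50.8 CPM. Has1, a hyaluronan synthase, fell from 66.9 ± 15.3 to 5.74 ± 4.22 CPM, and Vegfa, the angiogenic factor, from 677 ± 99.4 to 278 ± 27.1 CPM. Hey2, a Notch target, rose by 1.98 ± 0.30, Rspo3, a Wnt potentiator, by 3.23 ± 0.65, and Igf2, a growth factor, by 3.39 ± 0.59. Xist, the RNA of the inactive X chromosome, stood 4.04 ± 0.91 higher at 6 h, with 0.436, 2.41 and 2.11 CPM in the 3 PNU libraries at 6 h. The number of genes changed was 1106, 618 and 566 without PNU at 2 h replicates 1, 2 and 3, and 1710, 798 and 901 without PNU at 6 h replicates 1, 2 and 3. With near-identical libraries summed edgeR called 0, with 2114 at an unadjusted p under 0.05; DESeq2 called 3992 and limma-voom 2564.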

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

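The tests of swapped labels, a single wrong label, an effect alike in every culture, other cells, carried-over reads and sex, and the relabelings that keep near-identical libraries together, were chosen only after the result was seen; the GC-content test and the counts of all other splits had their predictions written before. Of the 6 genes whose PNU effect differed between 6 h and 2 h by an interaction term, Apln differed by -1.0 ± 0.14 on the log2 scale (SE; edgeR adjusted p = 0.0432), Fnip2 by -0.85 ± 0.12 and Clmp by -0.78 ± 0.10. Cxcl1 differed by 1.14 ± 0.15, Parm1 by 0.92 ± 0.13 and Rab32 by 0.88 ± 0.11. All 6 calls ended when near-identical libraries were summed. Of 100 relabelings drawn from 200, 3 gave as many genes, the real one included, with 6 in the real labels and 1698 in the highest other. The other 2 of these 3 are close to the real labels with those at 2 h mirrored, which turns the averaged PNU effect into the difference, so they tell nothing about chance. For the averaged PNU effect 2 of the 100 gave as many genes, with 1545 in the real split and 1698 in the highest other. Most of these relabelings part near-identical libraries, which are not exchangeable, so these shares do not exclude chance. Only 8 relabelings keep such libraries together, too few for a share under 0.05. The split with 1698 genes for the average exchanges PNU at 2 h replicate 1 with DMSO at 2 h replicate 3 and keeps the other 10 labels, so it still holds most of the treatment contrast. The splits are too few for a share under 0.05 at 2 h (real 50, highest other 0, as large in 1 of 10 splits), at 6 h (181 and 0, 1 of 10), for time in PNU (2759 and 0, 1 of 10) and for time in DMSO (0 and 0, 10 of 10).

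The first pattern is that DMSO at 2 h replicate 3 and PNU at 6 h replicate 1 lay nearest to libraries of the other treatment. Against exchanged labels within a time, 0 libraries of the opposite groups lay nearer on average to the other treatment, although the nearest library to PNU at 2 h replicate 1 was DMSO at 2 h replicate 3. A GC-content trend is also argued against, since after its removal both, 2 of 2, kept a nearest library of the other treatment, at 0.401 and 0.483. A single wrong label stays open. It could account for the distance of 0.405 from DMSO at 2 h replicate 3 to its nearest library. So could a culture that responded unlike its group, or a difference between cultures in their origin. DMSO at 2 h replicate 3 and PNU at 2 h replicate 1 both held Ddx3y (5.05 and 2.33 CPM), Thy1 (22.1 and 16.8 CPM) and Aldh1a3 (61.0 and 41.5 CPM). In the other libraries at 2 h these genes stood at most at 0.0889, 0.978 and 4.43 CPM. They were picked after their values were seen, so these sources cannot be told apart. An exchange across the times, between DMSO at 2 h replicate 3 and PNU at 6 h replicate 1, was not tested.

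The second pattern is that Six3, Sox2 and Pax6, which specify the eye field, were above 1 CPM in 4 of 6 PNU libraries. If the labels are right, the levels of these 3 genes were not alike in all PNU libraries. The genes were picked for this difference, so it gives no test of whether the compound acted alike in every culture. They stood at 0.254 to 0.6 CPM in PNU at 2 h replicate 1 and at 0.0873 to 0.279 CPM in PNU at 6 h replicate 1. The other 4 PNU libraries held them at 8.45 to 15.2 CPM. The count of 2 PNU libraries with all 3 genes under 1 CPM is part of the pattern and adds no separate test. Other cells present in some cultures may account for it, and the ratio of Pax6 to Six3 varied by 1.31 times among the 4 libraries. These form 2 near-identical pairs and the genes were picked for the pattern, so this cannot be told apart from a response in those cultures.

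The third pattern is that Y-linked genes, with Ddx3y at 2.33 to 7.30 CPM, were above 0.5 CPM in 4 libraries from 3 groups: PNU at 2 h replicate 1, DMSO at 2 h replicate 3 and PNU at 6 h replicates 2 and 3. Reads carried over from PNU at 6 h replicate 2 are argued against, because the Ddx3y share of 69.2% in DMSO at 2 h replicate 3 would bring Pax6 to 8.30 CPM, and 0.205 CPM was measured. Cultures from animals of different sex may account for it, with 3 groups holding libraries with and without these transcripts, but the labels give no sex, and Xist at 2.41 and 2.11 CPM in PNU at 6 h replicates 2 and 3 shows both kinds of transcript in 1 library.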

How the results depend on the processing

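The GC-content correction, the summing of near-identical libraries and the exclusion of both libraries that stood apart were chosen after the data were seen; that exclusion picks libraries by their outcome, so its counts are inflated by selection. Unless stated, the cause was not tested. In the order PNU effect at 2 h, at 6 h, averaged, its difference between times, time in DMSO and time in PNU, the reported counts were 50, 181, 1545, 6, 0 and 2759. DESeq2 gave 2511, 923, 3225, 279 and 23 for the first 5. Summing near-identical libraries, which leaves 8 libraries and 4 residual degrees of freedom, gave 0 for all 6 (209 and 54 at an unadjusted p under 0.05 for the difference between times and time in DMSO). Leaving out both libraries gave 9080, 4981, 9301, 3788, 117 and 6170. A minimum fold of 1.2 gave 0, 63, 114, 0 and 599 without time in DMSO, where it stayed at 0. GC correction gave 614, 336, 2528 and 31 for the first 4. No filter gave 140 at 2 h, 957 averaged and 15 for the difference, limma-voom 996 averaged, and the contrast's libraries alone 0 at 2 h (2926 unadjusted), 1646 at 6 h and 5311 for time in PNU. Leaving out 1 library gave 0 to 7724, 22 to 1057, 98 to 7672, 0 to 2947, 0 to 4 and 566 to 1710. The replicate block gave 311, 296, 2373 and 0 for the first 4, and 15 lists at 2 h and 11 at 6 h. Same-numbered libraries correlated at -0.31 to 0.42, 4 of 18 pairs over 0.1, and other numbers at up to 0.44. The highest of these correlations involve the libraries that stood apart, so they do not settle whether the numbers pair the samples. Y-linked genes differed within a number. In replicate 2 Ddx3y stood at 0.0889 and 7.30 CPM with PNU at 2 h and 6 h, and at 0.0374 and 0.037 CPM with DMSO. In replicate 3 it stood at 0.0154 and 6.67 CPM with PNU, and at 5.05 and 0.138 CPM with DMSO. These values argue against 1 culture behind all libraries of a number. Replicates 2 and 3 of both PNU groups shared transcripts such as Sox2, which replicate 1 of both held far lower. Upper-quartile scaling moved the share of higher calls for time in PNU from 46.1% to 63.0% and for the difference from 50% to 75% of 4 genes; GC correction moved it at 2 h from 72% to 46.7%. The largest shift of the median gene by a scaling was 0.0731, for time in PNU with upper quartiles.

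Of 9, 7 and 6 lists called at 2 h, at 6 h and for time in DMSO, an estimated correlation left 0, 0 and 1 and fry 4, 0 and 1; leaving out both libraries gave 19, 12 and 12. Leaving out 1 library gave 11 to 18 at 2 h. For time in DMSO the list test turned direction for G2 and M phase without DMSO at 2 h replicate 3 (median 0.0385; -0.468 to 0.0385 over single libraries left out) and without both libraries (0.0418). It also turned for stress response without both (median -0.0141, still negative) and for mitochondrial genes without DMSO at 2 h replicate 1 (-0.0626; -0.0626 to 0.386), all with adjusted p-values of 0.081 to 0.889. No named gene turned direction in any alternative run. All 202 calls on genes taken by the naming rule and 1 of 22 calls on lists ended when near-identical libraries were summed. Of the 202, 118 ended with the minimum fold, 36 with no filter, 30 with limma-voom, 10 with the replicate block and 3 after GC correction. With the contrast's libraries alone 26 of 184 ended. Depth, at 44332013 counts or more, limits genes near or under 0.0677 CPM.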

Other observations

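All of the comparisons of single genes given here as values were chosen after the result was seen, and no explanation was tested for them. Cxcl14, a chemokine of skin and mesenchyme, stood at 146.5 CPM in PNU at 2 h replicate 1, 171 CPM in DMSO at 2 h replicate 3, and 384 and 374 CPM in PNU at 6 h replicates 2 and 3, against at most 5.95 CPM in the other 8 libraries. The Hox genes Hoxc8 (1.66, 3.33, 2.47 and 2.14 CPM, in the same order) and Hoxb7 (0.646, 1.01, 1.12 and 1.02 CPM) followed these libraries. Thy1, a surface protein of neurons and fibroblasts, stood at 16.8 and 22.1 CPM and Aldh1a3, a retinoic acid enzyme, at 41.5 and 61.0 CPM in PNU at 2 h replicate 1 and DMSO at 2 h replicate 3, against at most 4.05 and 4.43 CPM elsewhere.

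Asb5, a muscle gene, stood at 26.7 and 24.4 CPM in PNU at 6 h replicates 2 and 3 and at most 1.69 CPM in the other 10 libraries, and Pax7, a muscle stem cell factor, at 1.53 and 2.36 CPM against at most 0.284 CPM. The imprinted growth genes H19 and Igf2 stood at 49.8 and 52.6 CPM and at 15.7 and 17.1 CPM in those libraries; H19 was at most 2.68 CPM and Igf2 at most 1.38 CPM in PNU at 2 h and DMSO at 2 h replicate 3. Shh, the morphogen sonic hedgehog, stood at 5.82 and 6.10 CPM in PNU at 2 h replicates 2 and 3 and at 2.92 and 3.19 CPM in PNU at 6 h replicates 2 and 3, and at 0.346 CPM or less elsewhere.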
